A study of Rattus norvegicus with 10 samples.

How the data were processed

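Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in RCS cells, a cell line from a rat chondrosarcoma. Per the labels, 6 of the 10 samples are immunoprecipitations, with 1 library each for SOX9, SOX6, H3K27ac, H3K4me1, H3K4me3 and H3K9me3. The other 4 are input libraries, made without an antibody, for SOX9, for SOX6, for H3K27ac and for the 3 methylation marks together. With 1 library per antibody there is no replicate error, and the tests below describe these libraries and not biological replicates.

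The immunoprecipitations were deposited as peak lists, 1 per library and not pooled, and the peak names in them carry the name of MACS, a peak caller. The submitters' processing notes name CASAVA 1.8 and the rat genome build rn5. The version and settings of the peak caller, the input set against each list, the aligner and any filter on reads are not given in the sources used here. Each peak has a score that the authors deposited. The lowest score is close to 50 in every list and many peaks share the value 3100, with a few above it, up to 3233. The scale of the score is not given in the sources used here, so it was used within each list, to order, group and describe its own peaks. Between lists only the ranks of peaks were compared. The inputs were deposited as a count of aligned reads per chromosome, split by strand and by the number of mismatches, with a further line for unmatched reads. These read counts are raw and were not normalised by the authors, per the file headers. No read depth was used here for the immunoprecipitated libraries.

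Peaks were read as intervals counted from 0, and coordinates are printed counting from 1 on rn5. All deposited peaks lie on 21 chromosomes, the 20 autosomes and X. Chromosome lengths were not used here, so the last peak end on each chromosome over all 6 lists stood in for its length (2902 Mb in all). Overlap meant at least 1 bp in common. Each overlap was set against 1000 circular rotations of the first list within each chromosome, which keep the widths and the spacing of its peaks. The p-value, a permutation p, is the rank of the observed count among the rotations, one-sided for more overlap, and the smallest that 1000 rotations can give is 0.001. P-values were adjusted by the Benjamini-Hochberg method over the 10 overlaps of SOX peaks and, separately, over the 12 ordered pairs of histone marks. Fewer overlaps than chance were described by the rank at the other end. Shares carry Wilson 95% intervals, rates exact Poisson intervals, rate ratios conditional binomial intervals, and the share of pairs of peaks in which the shared peak scores higher a bootstrap interval. These cover counting error only, and neighbouring peaks are not independent, so they are too narrow as a measure of what another library would give.

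Peaks that overlapped a peak of the other factor were called shared. They were compared with the rest within quintiles of the score, formed within each list. SOX9 and SOX6 peaks no more than 12.5 kb apart were joined into clusters, and the number of clusters with 5 or more peaks was set against 1000 rotations of the SOX6 list, with the SOX9 list in place. H3K27ac peaks were joined over the same distance into stitched regions. The planned ranking by score times width applied only if the score was a signal, and the stated fallback, the summed length covered by H3K27ac peaks, was used because no source used here shows that it is. The ranked curve was divided where its scaled slope is 1, and the regions above that point are called top-ranked. They are not called super-enhancers, since that term rests on read signal.

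The groups, the tests and most alternatives were fixed before the data were examined. So was the rule for what is named: the 10 highest-scoring peaks of each factor, the 10 clusters with most peaks, the 10 highest-ranked stitched regions and the 5 widest H3K9me3 domains, with ties ordered by coordinate. A planned comparison of gene lists was not run. An annotation of rn5 was not used here, and the gene table at hand is on GRCr8, so no region was assigned to a gene. The distances between peak centres, the position of centres inside marks, the classes of chromatin, the score classes of the marks, the comparison over chromosomes and 4 alternatives for the stitched regions were added after the data had been seen.

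For the comparison over chromosomes, input reads without a mismatch per Mb were divided by the median chromosome in each input library and averaged over the 4 libraries. Peak density was correlated with this value by Pearson's r and Spearman's rho, with 100000 permutations each and adjustment over the 6 lists. The rotation test was tested on simulated lists with the numbers (14782 and 19355) and widths of the SOX9 and SOX6 peaks. These were placed at random over the chromosomes without clustering, with 200 rotations for each pair. Of 20 independent pairs of lists, 1 gave p below 0.05. With 30% of peaks planted on the second list as exact copies, the mean excess over chance was 29.8% and all 20 pairs passed. This checks the computation and does not give the error rate for lists whose peaks cluster. Alternatives were a stricter overlap, peak centres, only the peaks above the median score of each list, narrowed peaks, equal numbers of peaks, placement inside active chromatin, other joining distances and other rankings of regions. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.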

Results

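Binding of SOX9 and SOX6 was mapped in RCS cells together with 4 histone modifications. SOX9 is the transcription factor that directs chondrocyte differentiation, and SOX6 is a related factor that acts with it in cartilage. H3K27ac marks active promoters and enhancers, H3K4me1 marks mainly enhancers, H3K4me3 marks mainly promoters and H3K9me3 marks heterochromatin. The series asks whether the SOX factors act at the same places in the genome and whether these lie in large enhancer regions.

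The SOX9 list held 14782 peaks with a median width of 538 bp, and the SOX6 list held 19355 with a median width of 460 bp. H3K27ac gave 50834 peaks that cover 82.3 Mb, H3K4me1 gave 92421 over 116 Mb, H3K4me3 gave 23116 over 39.6 Mb and H3K9me3 gave 52431 over 45.1 Mb. A single value of the authors' peak score, 3100, was shared by 41.9% of the H3K4me3 peaks and 18.4% of the H3K27ac peaks, and by 16 SOX9 and 26 SOX6 peaks. The input libraries held 131858579 reads for SOX9, 78052139 for SOX6, 36873004 for H3K27ac and 38604970 for the 3 methylation marks, of which 53.4% to 53.5% aligned. Each antibody has 1 library, so no value below has a replicate error.

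SOX9 and SOX6 occupied many of the same sites. Of the SOX9 peaks, 8329 overlapped a SOX6 peak, which is 56.3% (95% Wilson interval 55.5% to 57.1%). Of the SOX6 peaks, 8543 overlapped a SOX9 peak, or 44.1% (43.4% to 44.8%). The centres of shared peaks lay close together, with a median distance of 54 bp (quartiles 18 and 119 bp) between a shared SOX9 peak and the nearest SOX6 centre. Rotations placed 0.859% of SOX9 peaks on a SOX6 peak on average and 1.13% at most, and 0.670% of SOX6 peaks on a SOX9 peak on average and 1.31% at most. None of the 1000 rotations reached the observed counts (permutation p = 0.001, the smallest they can give; adjusted p = 0.00125 over 10 overlaps). Much of the genome carries neither active mark, and when peaks were placed at random inside the 143 Mb covered by H3K4me1 or H3K27ac, the chance shares rose to 12.7% for SOX9 and 10.3% for SOX6. The observed shares exceeded the highest of these placements, 13.6% and 11.2%. The placements did not follow the score of the marks, while both factors were more frequent in high-scoring H3K27ac peaks. SOX9 was present in 54.4% of H3K27ac peaks of the highest score class and 5.99% of those below the median score. For SOX6 the shares were 55.5% and 9.34%. The placements therefore do not account for a preference of each factor for high-scoring H3K27ac peaks.

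Sharing followed the score of the peak. In the lowest quintile of score 21.0% (19.6% to 22.5%) of SOX9 peaks met a SOX6 peak, and in the highest quintile 95% (94.1% to 95.7%) did. For SOX6 the share with SOX9 went from 15.8% (14.7% to 17.0%) to 82.5% (81.3% to 83.7%). The median score was 151 (quartiles 82.5 and 328) for shared and 63.6 (54.5 and 86.3) for unshared SOX9 peaks, and 195 (100.2 and 404) and 75.9 (58.6 and 122) for SOX6 peaks. A shared SOX9 peak ranked above an unshared one in 81.8% of all pairs (bootstrap 95% interval 81.1% to 82.4%), and a shared SOX6 peak in 78.1% (77.4% to 78.7%). Across the 8329 shared SOX9 peaks, the ranks by score within each factor had a correlation of 0.472. This is a correlation across sites within a pair of libraries, and sites are not independent replicates.

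The 10 highest-scoring peaks of each factor all overlapped the other factor and H3K27ac. Of the 10 SOX9 peaks, which were the first by position among 16 with a score of 3100, all 10 also met H3K4me1, 6 met H3K4me3 and 1 met H3K9me3. Of the 10 SOX6 peaks, 9 met H3K4me1, 5 met H3K4me3 and 0 met H3K9me3. A site on chromosome 4 entered both sets, as a SOX9 peak from 26336113 to 26337537 and a SOX6 peak from 26336130 to 26337502 (rn5). The last places of the SOX6 set went by position among 26 peaks with a score of 3100, so ties alone limit this match. Other SOX9 peaks of the set also met a SOX6 peak with a score of 3100. They start at 226072307 on chromosome 4, at 37326806 and 99628423 on chromosome 7 and at 17756196 on chromosome 9. The SOX6 peak with the highest deposited score, 3220, lay on chromosome 2 from 82976305 to 82977486. The next lay on chromosome 10 from 101371623 to 101372830, chromosome 8 from 77664353 to 77665636 and chromosome 4 from 230276717 to 230277645. The scale of the score is not given, so scores above 3100 cannot be read as stronger binding than the shared value of 3100. The peaks on chromosomes 8 and 4 met SOX9 peaks with scores of 85.8 and 101. Those on chromosomes 2 and 10 met SOX9 peaks with scores of 2605 and 1844.

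Most SOX peaks lay in active chromatin. H3K27ac overlapped 80.2% of SOX9 peaks (79.6% to 80.8%) and 75.7% of SOX6 peaks (75.1% to 76.3%), against rotation means of 4.22% and 4.04%. H3K4me1 overlapped 74.8% and 74.3% (rotation means 6.48% and 6.15%), and H3K4me3 39.8% and 39.2% (2.01% and 1.92%). No rotation reached any of these 6 counts (permutation p = 0.001, adjusted 0.00125). Between SOX peaks above their median score and H3K4me3 peaks above theirs, the share was 17.2% for SOX9 and 21.3% for SOX6. Against all H3K4me3 peaks it went from 29.2% in the lowest to 46.1% in the highest quintile of SOX9 score, and from 28.0% to 46.9% for SOX6.

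**Figure D1:**
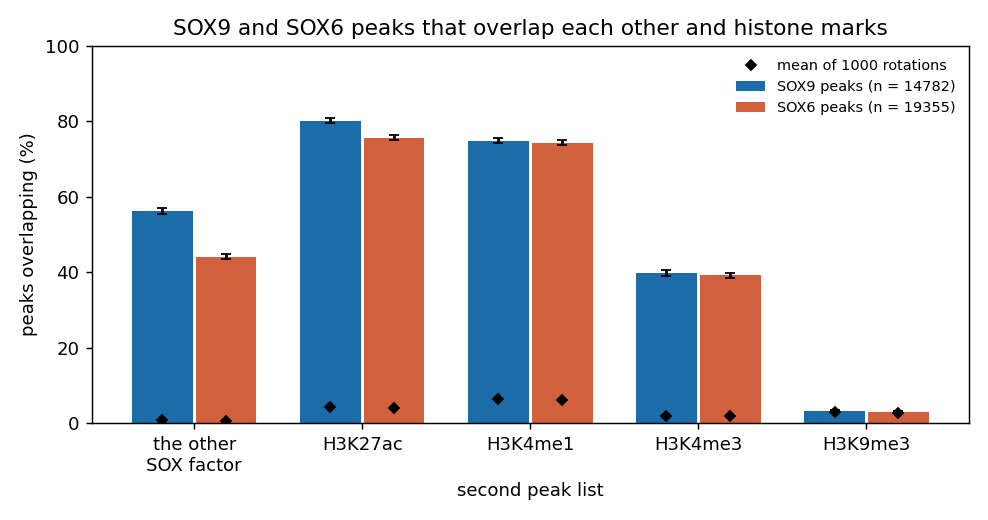
Share of SOX9 peaks (n = 14782, blue) and SOX6 peaks (n = 19355, orange) that overlap a peak of the other factor or of each histone mark, in percent, with Wilson 95% intervals; diamonds are the means of 1000 rotations. The shares with H3K27ac were 80.2% and 75.7%, and those with H3K9me3, 3.31% and 3.01%, lay close to the rotation means of 2.97% and 2.79%.

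H3K9me3 was met by 3.31% of SOX9 peaks (3.04% to 3.62%) and 3.01% of SOX6 peaks (2.78% to 3.26%), little above the rotation means of 2.97% and 2.79%. For SOX9, 44 of 1000 rotations gave as many overlaps (permutation p = 0.0450, adjusted 0.04995), and this call was lost between peaks above the median score of each list (2.16%, permutation p = 0.0899) and with SOX9 peaks narrowed to 400 bp (2.82%, p = 0.0539). It held for SOX9 centres inside H3K9me3 peaks (2.29%, permutation p = 0.002) and for an overlap of 0.5 of the narrower peak (2.56%, p = 0.004). For SOX6, 106 rotations did (permutation p = 0.107), while 2.26% of SOX6 centres lay inside H3K9me3 peaks, more than in any rotation (p = 0.001).

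By combination of marks, SOX peaks fell mainly into sites with H3K4me3 and sites with H3K27ac and H3K4me1 but no H3K4me3. The first class held 39.8% of SOX9 and 39.2% of SOX6 peaks, and the second held 39.1% (38.3% to 39.9%) and 36.2% (35.5% to 36.8%). H3K4me1 alone of the 3 active marks was present at 6.68% (6.29% to 7.10%) of SOX9 peaks and 10.6% (10.2% to 11.1%) of SOX6 peaks. None of the 4 marks was called at 11.5% of SOX9 and 11.3% of SOX6 peaks. These unmarked peaks had low scores, with medians of 55.7 and 59.1, and 4.34% (3.47% to 5.42%) and 3.38% (2.70% to 4.22%) of them met the other factor.

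Shared SOX peaks carried H3K27ac more often than unshared ones. An unshared peak is one without a deposited peak of the other factor, which may still bind there below the lowest score of its list. Of shared SOX9 peaks 93.6% overlapped H3K27ac, against 63.0% of unshared ones, a difference of 30.6 percentage points (29.3 to 31.9). For SOX6 the shares were 93.6% and 61.5%, a difference of 32.1 points (31.1 to 33.2). H3K4me1 showed the same order, at 88.8% and 56.9% for SOX9 and 87.6% and 63.9% for SOX6. H3K4me3 differed less, at 43.8% and 34.6% for SOX9 and 44.1% and 35.4% for SOX6. H3K9me3 went the other way, at 2.70% (2.37% to 3.07%) of shared and 4.11% (3.65% to 4.62%) of unshared SOX9 peaks.

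Since shared peaks also scored higher, the comparison was repeated within quintiles of the score. A quintile still spans a range of scores (244 to 3100 in the highest of SOX9), and peak width was not matched. The quintiles are of a peak's own score, so they do not account for binding of the other factor below its lowest score. Shared peaks were wider, with medians of 649 bp against 417 bp for SOX9 and 584 bp against 381.5 bp for SOX6. In the lowest quintile of SOX9 peaks, H3K27ac was present at 83.6% (80.5% to 86.3%) of shared and 43.9% (41.9% to 45.9%) of unshared peaks. In the highest quintile the shares were 98.0% (97.4% to 98.4%) and 91.9% (86.4% to 95.3%), the latter over only 148 peaks. For SOX6 they were 88.7% and 44.3% in the lowest quintile and 97.2% and 80.9% in the highest. Between peaks above the median score of each list the SOX9 difference was 10.03 points, against 26.7 points for SOX6. Here the list of the other factor and the H3K27ac list were cut too. Peaks that met only lower-scoring peaks of these lists counted as unshared or as without H3K27ac, unlike in the quintiles.

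**Figure D2:**
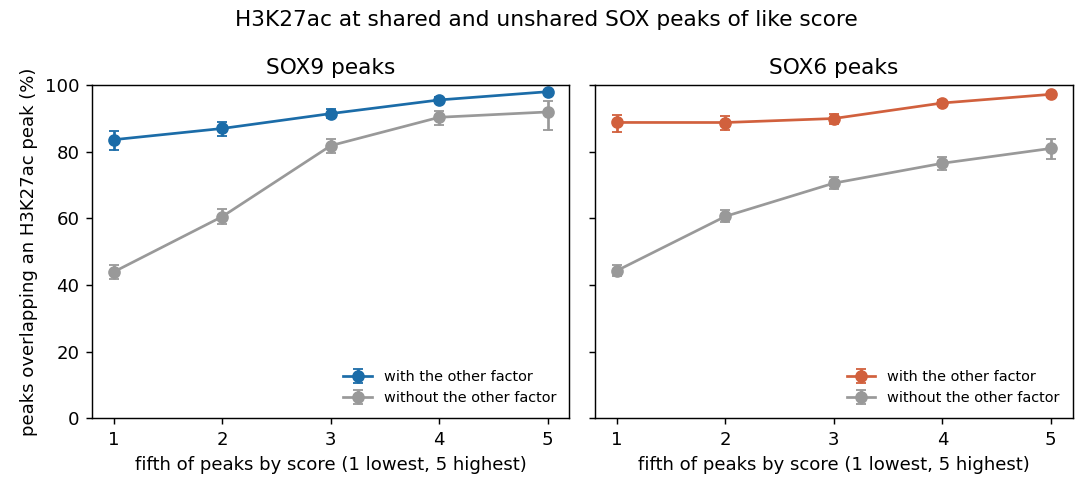
Share of SOX9 peaks (left) and SOX6 peaks (right) that overlap an H3K27ac peak, in percent, by quintile of the peak score, for peaks with and without a peak of the other factor; bars are Wilson 95% intervals. Shared peaks lay above unshared peaks in each quintile, for example at 83.6% and 43.9% in the lowest quintile of SOX9 and 98.0% and 91.9% in the highest.

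SOX9 and SOX6 peaks together formed clusters. Joining peaks within 12.5 kb gave 17215 clusters, of which 1091 held 5 or more peaks, against a mean of 495 and a highest value of 544 in rotations of the SOX6 list (permutation p = 0.001). The number was 627 with peaks joined within 5 kb (highest rotation 202) and 342 between peaks above the median score of each list (119). The rotations keep the spacing within each list, so this excess speaks only of the lists lying together and does not test whether peaks of 1 factor lie in groups. A SOX9 and a SOX6 peak at the same site counted as 2 peaks, so the overlap of the lists by itself raises the number. The clusters of 5 or more held 22.3% of SOX9 and 22.1% of SOX6 peaks, and 146 of them held 10 or more. Every cluster of 10 or more had both factors, compared with 82.7% of clusters of 2. More peaks give more chances to include both, and these shares were not set against rotations. H3K27ac was present in 48.5% (47.4% to 49.5%) of single peaks, 88.1% of clusters of 2 and 99.3% (96.2% to 99.9%) of clusters of 10 or more, while it covered 55.9%, 47.4% and 61.2% of their length. H3K9me3 was present in 3.22% of single peaks and 56.2% (48.1% to 64.0%) of clusters of 10 or more, and it covered 2.97% and 7.68% of their length. The median length was 380 bp for single peaks and 28561 bp for clusters of 10 or more.

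The cluster with most peaks lay on chromosome 9 from 29242722 to 29323280 (rn5) and held 11 SOX9 and 20 SOX6 peaks in 80.6 kb. H3K27ac peaks covered 91.0% of it, H3K4me1 peaks 89.2% and H3K4me3 peaks 26.4%, while H3K9me3 covered none of it. A pair of clusters stood close together on chromosome 2, from 218096984 to 218126699 with 25 peaks and from 217974481 to 218033886 with 21 peaks, with H3K27ac over 34.4% and 20.8% of their length. The cluster on chromosome 4 from 198304000 to 198387813 held 23 peaks and carried H3K4me1 over 59.2% and H3K4me3 over only 0.704% of its length. That on chromosome 1 from 258333164 to 258396971 held 22 peaks. The remaining 5 of the 10 largest held 19 or 20 peaks each. They lay on chromosome 16 from 53899254 to 53951829, chromosome 17 from 45665523 to 45708133, chromosome 4 from 64746975 to 64809318, chromosome 7 from 26816793 to 26842341 and chromosome 10 from 74131600 to 74151389.

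**Figure D3:**
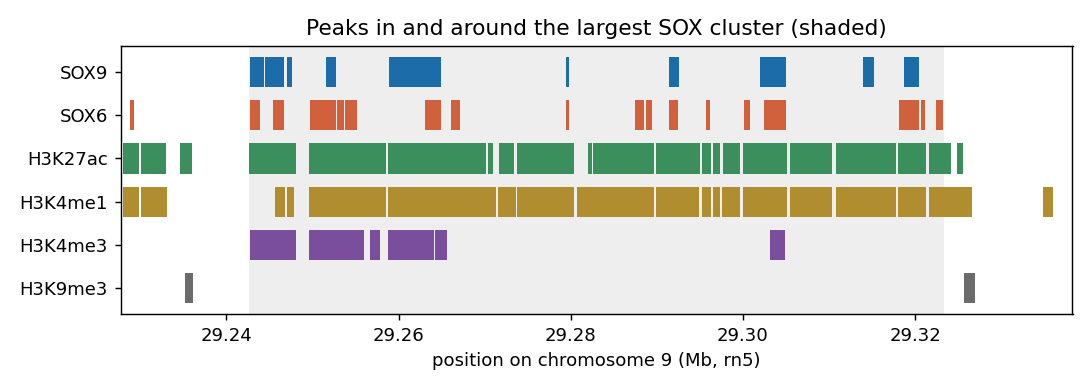
Peaks of SOX9, SOX6 and the 4 histone marks on chromosome 9 in and around the cluster from 29242722 to 29323280 (shaded), by position in Mb on rn5; each block is 1 deposited peak drawn to scale. The shaded cluster holds 11 SOX9 and 20 SOX6 peaks and H3K27ac peaks cover 91.0% of it.

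Large acetylated regions nearly always held both factors. The H3K27ac peaks formed 1019 stitched regions that were top-ranked by covered length and 21265 others, with median lengths of 42832 bp and 2154 bp. SOX9 was present in 96.2% (94.8% to 97.2%) of top-ranked and 32.9% (32.2% to 33.5%) of other regions, SOX6 in 96.0% (94.6% to 97.0%) and 37.3% (36.6% to 37.9%), and both in 93.3% (91.6% to 94.7%) and 23.9% (23.3% to 24.5%). Rotations put SOX9 in 19.5% of top-ranked and 2.80% of other regions, and SOX6 in 22.5% and 3.37%. Top-ranked regions held 22.1% of SOX9 peaks, 20.6% of SOX6 peaks and 29.4% of the H3K27ac-covered length. They overlapped 8 of the 10 largest SOX clusters. Large clusters are long and nearly all hold H3K27ac, and this number was not set against rotations or smaller clusters.

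Per length, however, peaks were not denser there. Top-ranked regions held 0.644 SOX9 peaks per 10 kb (0.622 to 0.666) and other regions 0.769 (0.753 to 0.786), a rate ratio of 0.837 (0.804 to 0.871). For SOX6 the rates were 0.785 and 0.965, a ratio of 0.814 (0.785 to 0.844). When base pairs under SOX peaks were counted in place of peaks, SOX9 peaks took up 5.33% of the length of top-ranked and 4.99% of that of other regions, a ratio of 1.07 (1.01 to 1.14, chromosomes resampled), so the direction turned. For SOX6 the ratio was 0.967 (0.912 to 1.02), an interval that includes 1.

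The region with the most H3K27ac-covered length lay on chromosome 7 from 26758609 to 26989346 (rn5), with 177 kb covered, 22 SOX9 and 27 SOX6 peaks, and 78 H3K9me3 peaks. The next were on chromosome 9 from 17522439 to 17791204 (132 kb covered, 9 SOX9 and 14 SOX6 peaks) and chromosome 1 from 141604049 to 141801076 (131 kb, 26 and 19). Chromosome 1 from 191831792 to 192009653 had 12 peaks of each factor, and chromosome 2 from 265564595 to 265767213 had 11 and 15. The largest cluster lay inside the region ranked 6, on chromosome 9 from 29193037 to 29325545 (13 and 25). The others of the first 10 lay on chromosome 10 from 74055836 to 74242680 (14 and 26), chromosome 5 from 83131010 to 83282686 (10 and 10), chromosome 9 from 44541553 to 44695722 (9 and 11) and chromosome 10 from 105800418 to 105957651 (9 and 12).

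The active marks coincided with one another, and H3K9me3 met H3K4me3 slightly less often than rotations gave. H3K4me1 overlapped 80.8% (80.5% to 81.2%) of H3K27ac peaks, and H3K4me3 38.7%. H3K27ac overlapped 85.4% of H3K4me3 peaks and 51.0% of H3K4me1 peaks. By length, 67.5% of H3K27ac-covered sequence was also under H3K4me1 peaks and 39.0% under H3K4me3 peaks, against 4.54% and 1.51% in rotations. Of H3K9me3 peaks, 1.72% (1.61% to 1.84%) met H3K4me3, below the rotation mean of 2.25% and below the lowest of 1000 rotations, 1.89%.

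H3K9me3 peaks met the other active marks more often than rotations gave. H3K27ac was met by 9.01% (8.76% to 9.25%), against a rotation mean of 4.70% and a highest rotation of 5.44%, and H3K4me1 by 9.44% (9.19% to 9.69%), against 7.30% and 8.41% (both permutation p = 0.001, adjusted 0.00120 over 12 pairs). Between peaks above the median score of each list the share with H3K27ac was 5.47%, against a rotation mean of 3.47%. The 5 widest H3K9me3 domains held few other peaks. The widest lay on chromosome 6 from 139205394 to 140088158, with 322 H3K9me3 peaks in 883 kb, 1 SOX9 peak and 0 peaks of SOX6 or the active marks. The others lay on chromosome 3 from 175607057 to 176385138 (317 peaks), chromosome 12 from 34425061 to 35165258 (254), chromosome 3 from 182445134 to 183154462 (323) and chromosome 6 from 140102087 to 140757476 (239). Each of these held 1 to 3 peaks of the other 5 lists together.

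Peak density differed between chromosomes and moved with the input. Relative to the median chromosome, input reads without a mismatch per Mb were 2.05 on chromosome 16, 2.03 on chromosome 9, 1.91 on chromosome 7 and 1.63 on chromosome 11, and 0.705 on chromosome 15, 0.712 on chromosome 20 and 0.595 on X. Over the 21 chromosomes, SOX9 peaks per Mb correlated with this value at r = 0.762 and rho = 0.873 (permutation p = 4e-05 and 1e-05, the latter the smallest the permutations can give; adjusted 0.00024 and 6e-05). The values were r = 0.734 and rho = 0.821 for SOX6 (adjusted p = 0.00046 and 7.5e-05), 0.653 and 0.642 for H3K27ac (0.002655 and 0.00252), and 0.716 and 0.794 for H3K4me1 (0.00046 and 6e-05). H3K4me3 showed no detectable relation (r = 0.308, rho = 0.355; adjusted p = 0.173 and 0.117), and H3K9me3 only one by rank (r = 0.425, rho = 0.799; adjusted p = 0.0706 and 7.5e-05). Without chromosomes 16 and 9, the farthest from the median, r was 0.775 for SOX9, 0.742 for SOX6, 0.597 for H3K27ac, 0.700 for H3K4me1, 0.358 for H3K4me3 and 0.287 for H3K9me3. X, lowest in input and in the density of every list, was kept in all of these correlations. No r over the autosomes alone is given here.

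Chromosome X held 1.08 SOX9, 1.49 SOX6 and 5.61 H3K4me1 peaks per Mb, below the lowest autosome, chromosome 15, at 3.25, 4.55 and 20.2. As a ratio of X to chromosome 15, the gap was smaller for H3K27ac (5.999 against 11.5), H3K4me3 (3.92 against 5.51) and H3K9me3 (4.43 against 8.23). Chromosome 10 was densest in SOX9 (8.90 per Mb), SOX6 (11.6) and the 3 active marks. Chromosome 12 was densest in H3K9me3, at 76.3 peaks per Mb against an autosome median of 16.4.

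**Figure D4:**
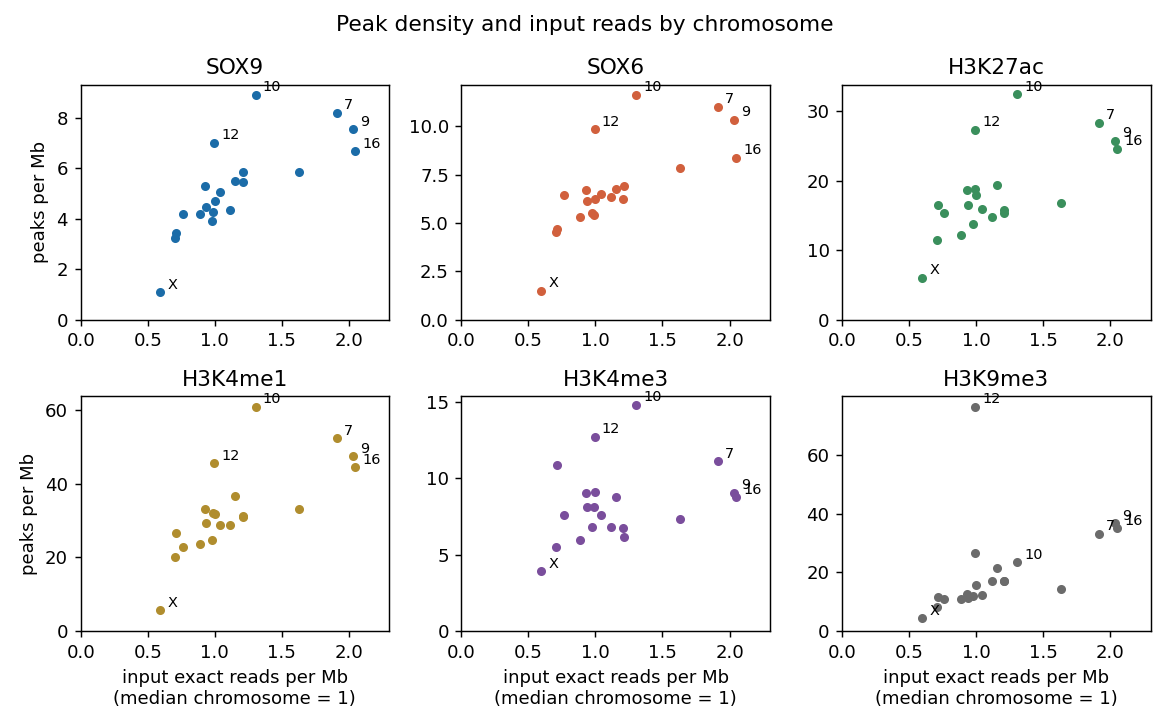
Peaks per Mb of each list against input reads without a mismatch per Mb, relative to the median chromosome and averaged over 4 input libraries; each point is 1 of 21 chromosomes, and 6 are named. Chromosomes 7, 9 and 16 lay at 1.91 to 2.05 on the horizontal axis and X at 0.595, and SOX9 density correlated with the input at r = 0.762.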

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

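These values were found by a search of the mismatched reads of the input libraries, which enter no comparison of the report, and the search was chosen after the data had been seen. On chromosome 11, more than 1 in every 2 aligned input reads had at least 1 mismatch. The share was 54.6% in the input for SOX9, 53.9% in the input for SOX6, 55.0% in the input for H3K27ac and 55.3% in the input for the 3 methylation marks. On the other chromosomes it lay between 10.4% and 33.3%, with chromosome 1 next highest in each library. The numbers on peak density above use only reads without a mismatch.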

How the results depend on the processing

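The alternatives were planned before the data were examined, apart from the ranking by score times width, the rate per H3K27ac-covered length and both counts of base pairs under SOX peaks, which were chosen after the result was seen. Over 29 results, 72 of 95 alternatives kept the direction and call of a test, stayed within the counting interval of a value with no test, or stayed within 1.5 times the number of clusters, among them 40 of 44 for SOX overlaps and 24 of 24 for pairs of marks. With 1 library per antibody no replicate could be left out. Listed genes and their alternatives were not run for want of an rn5 annotation. The use of all sequences changes nothing, as every peak lies on the 21 chromosomes.

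The SOX9 call with H3K9me3 was lost between peaks above the median score of each list (2.16%) and at 400 bp (2.82%) and held with an overlap of 0.5 of the narrower peak (2.56%) and with peak centres (2.29%), and that for SOX6 was gained under the same pair (2.38% and 2.26%). The cause was not tested. With every list cut at its median score, the H3K27ac difference of shared and unshared peaks was 10.03 points for SOX9 and 26.7 for SOX6. The same cut left 342 clusters with 5 or more peaks, from lists with fewer peaks. Joining within 5 kb, which splits clusters, left 627, and joining within 25 kb gave 1576. The highest rotations were 119, 202 and 1099, so each count kept its direction and call. With peak centres, a shared peak ranked above an unshared one in 81.0% of pairs for SOX9 and 77.003% for SOX6.

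The density ratio of top-ranked to other regions moved with the construction of the regions, and why was not tested here. For SOX9 it was 0.951 with regions joined within 25 kb, 0.704 without H3K27ac peaks that meet H3K4me3, 0.917 ranked by score times width, 0.896 per covered length, 1.14 by base pairs per covered length and 1.07 by base pairs per region length. For SOX6 it was 0.780 joined within 5 kb, 0.925 within 25 kb, 0.692 without H3K4me3, 0.892 by score times width, 0.872 per covered length, 1.04 by base pairs per covered length and 0.967 by base pairs per region length. Both SOX9 ratios by base pairs lay above 1, with their intervals, and both SOX6 intervals (0.980 to 1.09 and 0.912 to 1.02) included 1. The depth of the immunoprecipitated libraries is not known here, so differences in the length of the lists cannot be read as differences in binding.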

Other observations

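The tests on gaps, on wide peaks, on weak H3K9me3 peaks and on chromosome X were chosen after the result was seen. Those on promoters, on template DNA, on whole chromosomes and on the top-ranked regions were written down before their values were known. No group of the design gives a biological explanation for these patterns, and none was tested beyond the explanations named here.

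SOX peaks were denser in high-scoring than in low-scoring H3K27ac peaks, and less dense in high-scoring H3K4me3 peaks. H3K27ac peaks with a score of 3100 or more held 1.98 SOX9 peaks per 10 kb (Poisson 95% interval 1.93 to 2.02), and H3K27ac peaks below the median score held 0.739 (0.703 to 0.777). For H3K4me1 the rates were 1.56 (1.47 to 1.65) and 0.503 (0.479 to 0.528). H3K4me3 had the opposite order, with 1.05 (1.01 to 1.09) at 3100 or more and 2.60 (2.502 to 2.69) below the median score. SOX6 did likewise, with 2.23 and 1.17 per 10 kb under H3K27ac peaks, and 1.41 and 3.13 per 10 kb under H3K4me3 peaks. The H3K4me3 peaks of 3100 or more were wider (median 2383 bp against 897 bp), and equal shares of both classes held a SOX9 peak within counting error, 23.5% (22.7% to 24.4%) and 23.7% (22.9% to 24.5%). Of the 1725 H3K4me3 peaks above the median score but below 3100, fewer held a SOX9 peak, 17.5% (15.8% to 19.4%).

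Most SOX centres lay inside peaks of H3K27ac (78.8% for SOX9 and 73.9% for SOX6) and of H3K4me1 (65.2% and 66.9%). Of the SOX9 centres inside H3K27ac peaks 37.8% were in the middle 20% of the peak, as were 34.0% of SOX6 centres. Of the 5137 SOX9 centres outside H3K4me1 peaks, 23.6% (22.5% to 24.8%) had an H3K4me1 peak within 1000 bp on both sides, and 19.1% (18.2% to 20.1%) of 6397 SOX6 centres did. For centres outside H3K27ac peaks the shares were 1.72% (1.32% to 2.24%) and 1.76% (1.43% to 2.16%). These positions were not set against rotations.

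SOX9 peaks were less dense in top-ranked stitched regions than in others, at a ratio of 0.837. The gaps between H3K27ac peaks are not the whole cause, as the ratio per covered length was 0.896 (0.861 to 0.933), still below 1. Without H3K27ac peaks that meet H3K4me3 the ratio per region length was 0.704 (0.668 to 0.743), so it did not rise toward 1. Leaving out these peaks also changed how regions were joined and ranked and could add gaps to the region length. The test therefore cannot tell promoters from gaps and decides nothing about promoter regions among the others. It also stays open that neighbouring sites in strong regions may be called as 1 wide peak. Over the H3K27ac-covered length, the ratio of SOX9-covered base pairs was 1.14 (1.08 to 1.22). SOX6 gave 1.04 (0.980 to 1.09), which leaves either direction open.

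The density of SOX9, SOX6, H3K27ac and H3K4me1 peaks rose with input reads per Mb over the chromosomes, and that of H3K4me3 peaks did not detectably, nor that of H3K9me3 peaks by r. A candidate explanation for part of the rise of SOX9 is that more template DNA lifts weak peaks past the threshold of the peak caller. The slope of log2 density on log2 input was 1.14 for SOX9 peaks below the median score and 0.857 for those above it, a difference of 0.284 (0.119 to 0.532, chromosomes resampled), and over the autosomes alone 0.876 and 0.542, a difference of 0.334 (0.136 to 0.592). The higher-scoring peaks thus rose too (0.317 to 0.772 over the autosomes). If more template raises scores, it can also lift peaks past the median, so this split cannot tell such an effect from other causes. Differences in gene content were not tested and stay open. Fewer input reads do not account for the H3K4me1 density of X, at a log2 residual of -1.93 from the line of the autosomes (lowest autosome -0.35), and X also lay below the lowest autosome in the other 5 lists, by most for SOX9 (-1.63 and -0.28) and by least for H3K9me3 (-1.08 and -0.89).

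H3K9me3 peaks met H3K27ac more often than rotations gave. The share was 15.7% (15.1% to 16.5%) in the highest quintile of score of H3K9me3 peaks and 7.06% (6.58% to 7.56%) in the lowest. The overlap is thus not confined to weak H3K9me3 peaks. The quintiles were not set against rotations of their own and peak width was not matched, so background in open chromatin stays open. Against rotations, the overlap was 1.58 times the mean between peaks above the median score of each list and 1.91 times over all peaks. The overlap was 1.632 times the rotation mean on the 10 chromosomes below the median input and 2.03 times on the other 11. Rotations within a chromosome keep its number of peaks, so peak numbers raised by gain of a whole chromosome are not the source of this excess. Any other effect of such a gain is not decided by these values. The top-ranked regions held 44.1% of the overlapping H3K9me3 peaks, but outside them the overlap was still 1.634 times the rotation mean (highest rotation 1.14). Local gains of DNA and mixed cell populations were not tested and stay open.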
